A study of Arabidopsis thaliana and Oryza sativa and Zea mays with 33 samples.

How the data were processed

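Small RNAs of 33 libraries in 25 groups were analysed, 24 from Arabidopsis thaliana, 7 from rice and 2 from maize. The deposited tables list each distinct small RNA sequence with its raw read count, and no normalization had been applied. For 22 libraries the counts were taken after adapter removal per the labels, and TAIR10 is named for these libraries in the submitters' processing notes. For the 4 libraries of the earlier Arabidopsis flower set the notes name TAIR9, and for the 7 rice libraries no build is named. The trimming tools and filters were not given in the sources used here. The libraries of the main flower set were made with an Illumina small RNA kit, per the labels' protocols. No molecular identifiers are mentioned in the labels, so a read is not an independent molecule, and every interval and floor given here covers counting error only.

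Groups were taken from the labels. The main flower set held 4 groups of 3 libraries, the 12 replicated flower libraries, and the other 21 groups held a single library each. The labels do not say whether replicates came from separate plantings, so p-values measure the spread between these libraries, which may be technical. Pairs of libraries of one group differed by far more than sampling noise, with chi-square per degree of freedom between 10.9 and 54.6, and no library was counted as a duplicate. One input library is titled as heso1-1 hen1-8 while another of its labels names a hen1-9 allele, and the title was followed. The rice tissue is called leaf in one label and whole plant in the protocol. The maize mutant was in a B73xW22 background and the maize wild type in B73. The last line of the table for ago1-11 hen1-2 seedlings held no count and was left out.

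A read was assigned to a miRNA when it began at the 5′ end of the mature sequence and matched it up to at most 5 nt before the mature 3′ end. The template was continued by 12 genomic bases at annotated Arabidopsis loci, and bases past the longest match counted as a tail of at most 8 nt. A read was called truncated when its match ended 1 to 5 nt before the mature end, tailed when it carried such extra bases, and intact when it was neither. Thus 36 miRNAs were counted in Arabidopsis, 27 in rice and 19 in maize. Members that share a 5′ sequence, such as miR165 and miR166 or the copies of miR159, miR319, miR396 and miR398, were counted together, so their values are uncertain for any one member. A read that lost bases and gained U can equal another member, as in miR159 and miR396, and then counts as intact. A tail that equals the template is not seen either, so a miR165/miR166 read that lost 5 nt and gained U counts as 4 nt lost. Tailing and truncation of these miRNAs may thus be understated. No rice or maize genome was used here, so a rice or maize template ended with the mature sequence or, for a few members, with a longer read that was the most frequent in wild type, and a base that continues the precursor counts there as a tail. A few rice and maize mature forms were shortened by 1 nt where that read was the most frequent in wild type. Rice and maize miRNAs needed at least 50 wild-type reads.

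Reads of 21 nt were matched without mismatch to the transcripts of TAIR 10.1 on either strand, and those that matched a single gene were counted for 36575 genes. A 21-nt siRNA that lost bases or gained untemplated bases at its 3′ end is mostly missed by this rule. A lower count per gene can thus reflect changed ends as well as fewer siRNAs. A misread base also keeps a read from matching. In the replicated flower libraries with A read as C, described below, 4.57% to 9.72% of 21-nt reads matched a single gene. The share was 8.96% to 18.0% in the others, and higher there within every group. Mutants and controls of a comparison hold equally many affected libraries, but the Ler comparison holds more than the Col one. Levels per gene are thus not comparable between backgrounds. Reads shared between near-identical genes, miR171a itself among them, stay out of these counts, so levels of the related pentatricopeptide repeat genes are lower limits for the family. The library size was the number of reads of 18 to 28 nt, and levels are given as RPM, the count over this number times 1e6.

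Tests used edgeR 4.0.16 in R 4.3.3, with its quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05, in 1 fit over the 12 libraries with a coefficient per group. Abundance was tested on 27 miRNAs with a mean of at least 100 reads and on 572 genes with a mean of at least 10 reads. Tailing and truncation were tested as odds, with affected and unaffected counts side by side and a term per library. Each test covered hen1-1 against Ler, hen1-8 against Col, and the difference between both effects. Shares per library were compared with two-sided exact permutation tests, for which 3 libraries against 3 cannot give a p below 0.1. Shares of single libraries carry Wilson 95% intervals. Correlations across miRNAs used 100000 permutations, and miRNAs are not independent replicates. Where a group held 0 reads, a floor of 3 reads over the group was used. No scaling beyond library size was applied. The median log2 change of the tested miRNAs was 0.50 in hen1-1 and 0.49 in hen1-8, against 0.09 and -0.37 under TMM and 0.12 and 0.03 under DESeq2. For genes the medians were 0.57 and 0.76, against 0.10 and 0.00 under TMM and -0.12 and 0.11 under DESeq2.

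The lists of miRNAs and genes were fixed before the data were examined. The miRNA lists were conserved angiosperm families, Brassicaceae lineage miRNAs, regulators of the silencing machinery (miR162, miR168, miR403), triggers of secondary siRNAs, regulators of auxin signalling, nutrient-responsive miRNAs, developmental regulators, and miRNAs with a 5′ A or a 5′ C. The gene lists were TAS loci, the miR171 targets, targets of miR168, miR403 and miR162, the pentatricopeptide repeat genes known as siRNA sources, and targets of miR393, the ARF, class III HD-ZIP, SPL, AP2, TCP and MYB, GRF and NAC families and nutrient genes. Lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and with an estimated one.

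The named miRNAs were, per comparison, the 10 with the most reads, the 5 largest rises and 5 largest falls past the threshold, and the tested silencing regulators and siRNA triggers. For single libraries they were the 10 with the most reads and the 3 largest differences in each direction, among miRNAs with at least 100 reads in each library. The named genes were the 10 largest rises and 10 largest falls past the threshold with one direction in every replicate, the TAS loci, the miR171 targets and up to 4 members of each other list. Of these the most informative are printed, and names outside the rule are said to be so where they stand.

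In simulated data made from the means and sizes of these libraries, with 27 miRNAs, the abundance test recovered 3 of 6 true 2-fold changes and 6 of 6 true 4-fold changes for hen1-1, and the same numbers for hen1-8. The tailing test recovered 1 of 6 and 5 of 6 for hen1-1, and 0 of 6 and 3 of 6 for hen1-8. The truncation test recovered 2 of 6 and 6 of 6 for hen1-1, and 1 of 6 and 5 of 6 for hen1-8. For tailing and truncation the simulated spread between libraries was preset and not estimated from these libraries. Their recovered counts thus do not measure the power of the real tailing and truncation tests. With 572 genes, 8% of 2-fold and 52% of 4-fold changes were recovered for hen1-1, and 20% and 81% for hen1-8.

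The replicate numbers of the labels were checked for pairing. Deviations of same-numbered libraries correlated in abundance (r between 0.37 and 0.74) and in truncation (r between 0.23 and 0.51) for every pair, although in truncation 1 other pairing of hen1-8 libraries reached r = 0.397. In tailing r lay between -0.126 and 0.473. In reads per gene it was weakly positive, between 0.0150 and 0.212, and another pairing of hen1-1 replicate 2 reached r = 0.0295. For abundance and truncation the fit with the replicate number as a block therefore stands beside the main one where it changes a count of calls by over 1.5 times. Same-numbered libraries of a comparison were also alike in the reading of A as C given below. Its part in the pairing was not tested.

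Alternatives planned before the data were examined were all reads as library size, TMM, DESeq2 1.42.0, limma, no count filter, other limits of truncation, templates without genomic bases, tails of U alone, exact mature reads only, reads matching several genes, 20- to 22-nt reads, the replicate block, and leaving out each library in turn. Several choices were made after the data had been seen. Reads joined to an oligonucleotide were left out, templates were restricted to annotated loci, rice members and the rule for rice and maize mature forms were added, and the minimum of 50 wild-type reads was set. The joined reads averaged 1.79% of miRNA reads in Ler and 2.55% in Col, against 0.135% in hen1-1 and 0.163% in hen1-8. This filter thus fell mainly on the controls. In 6 of the 12 flower libraries (Ler 1 and 2, hen1-1 1 and 2, Col 1, hen1-8 1) between 4.27% and 5.33% of the A bases inside miRNA matches were read as C, against 0.00620% to 0.0208% in the other 6, and a threshold of 2% separated these runs. Keeping the joined reads, counting C over A as a match, a term for the run and values within runs were therefore added as alternatives. Further software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.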

Results

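Small RNA libraries were sequenced from mutants of HEN1, the methyltransferase that places a 2′-O-methyl group on the 3′ end of plant small RNAs, and from their controls. Immature flowers of the strong Arabidopsis allele hen1-1 and its background Landsberg erecta (Ler), and of the weak allele hen1-8 and its background Columbia (Col), gave 3 libraries per group. Total reads were 2374442, 5321574 and 6088853 in Ler, 2378069, 5791631 and 19140379 in hen1-1, 1928261, 9695464 and 2226455 in Col, and 4264177, 23722486 and 14077003 in hen1-8. The other groups held a single library each. Arabidopsis seedlings of Ler, hen1-2, ago1-11 and ago1-11 hen1-2 gave 33184725, 34286095, 29458728 and 29570957 reads. ARGONAUTE1 (AGO1), the main effector protein of miRNAs, was immunoprecipitated from hen1-8 and from heso1-1 hen1-8 flowers, which also lack the uridylyl transferase HESO1, with 24134854 and 11156077 reads and inputs of 25103758 and 27588154 reads. Only 5.32% and 5.05% of the input reads were 18 to 28 nt long, and the 10 most frequent sequences held 54.1% and 59.6% of each input library. Rice plants of waf1-1 and waf1-2, alleles of the rice HEN1 gene, gave 45297540 and 44151199 reads against 51198094 and 46055745 in their wild types. The rice allele oshen1-3 gave 15769908 reads, its wild type 23979621 and segregating heterozygotes 37538207. Maize hen1-1 and wild-type leaves gave 33477122 and 48831520 reads. An earlier single-library flower set held 20077183 reads of hen1-1, 21199268 of Ler, 10552612 of hen1-8 and 12270803 of Col. No library held over 0.79 RPM of 21-nt reads at HEN1 itself, which tests nothing about the genotypes.

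To ask how the loss of methylation changed the small RNA population of flowers, the length classes were compared first. The 21-nt class, which holds most miRNAs, made up 15.01% ± 2.07 (SD, n = 3) of the 18 to 28-nt reads in Ler and 9.70% ± 1.04 in hen1-1, and 13.3% ± 1.34 in Col and 9.22% ± 0.280 in hen1-8. The 24-nt class, mostly siRNAs of repeats, made up 34.8% ± 1.95 in Ler and 25.3% ± 1.52 in hen1-1. In Col and hen1-8 its shares were 31.5% ± 2.47 and 29.9% ± 0.398. The 23-nt class held 10.9% of reads in Ler and 15.3% ± 0.503 in hen1-1, and 11.4% in Col and 16.2% ± 0.0875 in hen1-8. The 21-nt differences of -5.32 and -4.09 percentage points and the 24-nt difference of -9.53 points in hen1-1 each reached p = 0.1 in the exact permutation test with n = 3, the smallest it allows, while the 24-nt difference of -1.57 points in hen1-8 had an exact permutation p of 0.4. Within the run with A read as C the 21-nt differences were -5.10 and -5.26 points and within the other run -5.75 and -3.51, and the 24-nt differences were -10.0 and -2.88 points and -8.54 and -0.907 points. As a share of all reads the 24-nt difference of hen1-8 turned to 4.60 points.

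The next question was how many miRNA reads had lost or gained bases at the 3′ end in each allele. Summed over miRNAs, 6.64% ± 1.20 (SD, n = 3) of reads carried a tail in Ler and 38.1% ± 6.81 in hen1-1, and 11.2% ± 2.82 in Col and 36.3% ± 1.75 in hen1-8. Reads that had lost 1 to 5 nt made up 8.46% ± 0.871 in Ler and 58.4% ± 1.74 in hen1-1, and 11.5% ± 2.58 in Col and 54.2% ± 1.29 in hen1-8. Intact reads were at 89.0% ± 1.62 in Ler, 30.4% ± 2.09 in hen1-1, 83.1% ± 4.60 in Col and 34.2% ± 1.97 in hen1-8. Reads that were truncated and then tailed made up 26.8% ± 3.49 in hen1-1 and 24.7% ± 1.57 in hen1-8, against 4.15% ± 0.451 and 5.72% ± 0.785 in the backgrounds. U made up 63.4% ± 10.7 of tail bases in Ler, 80.7% ± 7.02 in hen1-1, 72.4% ± 6.82 in Col and 83.7% ± 5.42 in hen1-8. With A read as C it was 56.2% and 58.4% in Ler, 78.1% and 75.4% in hen1-1, 64.5% in Col and 77.5% in hen1-8. In the other libraries it was 75.7% in Ler, 88.7% in hen1-1, 76.1% and 76.5% in Col, and 87.5% and 86.2% in hen1-8. The rises in tailing of 31.4 and 25.2 points and in truncation of 49.9 and 42.7 points each reached an exact permutation p of 0.1 with n = 3, the smallest possible. Within the runs with and without A read as C, tailing was higher by 27.9 and 38.5 points in hen1-1 and by 27.4 and 24.1 points in hen1-8, and truncation by 51.0 and 47.7 points and by 43.6 and 42.3 points.

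**Figure D1:**
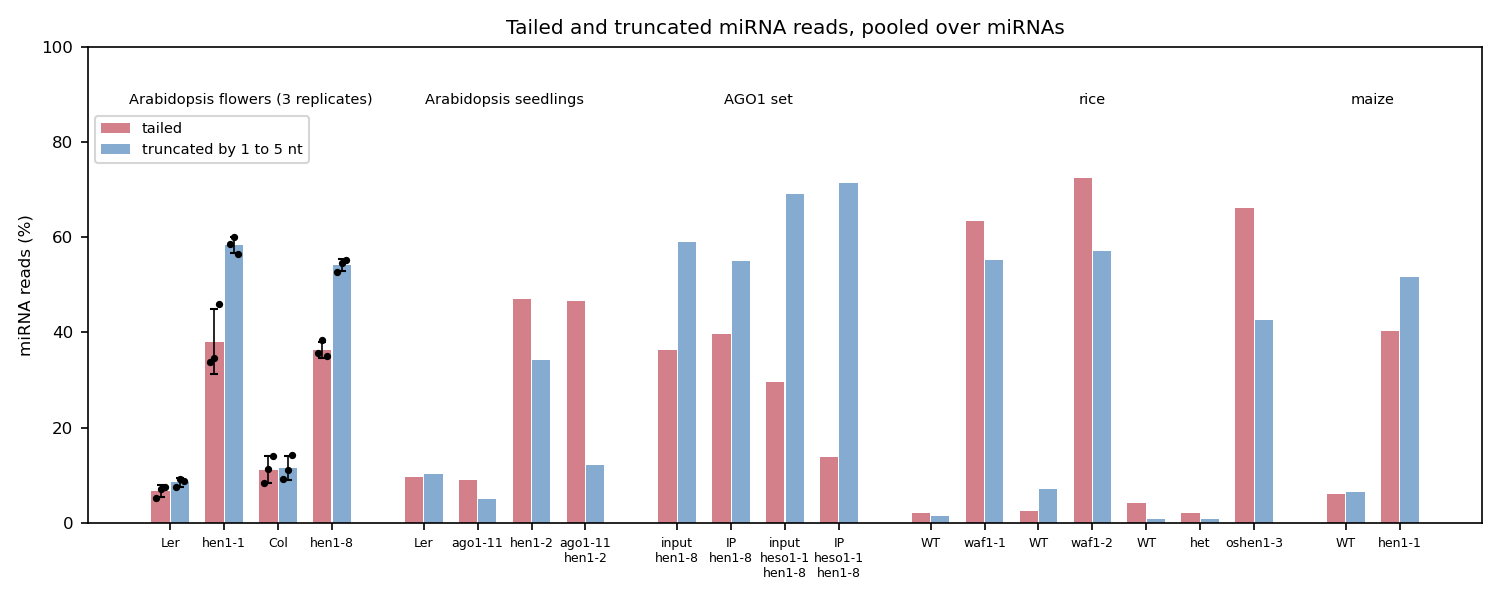
Percentage of miRNA reads that were tailed (red) or truncated by 1 to 5 nt (blue) per group, with bars for group values and, for the flower groups, points for the 3 libraries and error bars for the SD. Single libraries have no error bars; tailing was at 38.1% in hen1-1 flowers, 13.9% in the AGO1 precipitate of heso1-1 hen1-8 and 72.5% in waf1-2.

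Tailing differed widely between miRNAs of one plant. In hen1-1, miR824, a regulator of the stomatal gene AGL16, went from 13.1% to 92.4% tailed reads, with a log2 odds ratio of 6.53 (SE 0.59). For miR396, a regulator of GRF growth factors, the share rose from 1.12% to 22.9% (log2 4.72, SE 0.25, edgeR adjusted p = 9.32e-09), for miR159, a regulator of MYB factors, from 5.64% to 42.6%, for miR390 from 3.05% to 36.4%, and for miR165/miR166, regulators of class III HD-ZIP genes, from 0.996% to 12.4% (log2 3.82, SE 0.24, edgeR adjusted p = 2.99e-08). In hen1-8 the same miRNAs rose from 11.7% to 91.7%, from 1.94% to 22.7%, from 3.83% to 41.6%, from 4.20% to 30.7% and from 1.52% to 11.9%. The Col values of miR824 and miR159 rest largely on Col replicate 1, with 28.6%, 6.67% and 0% of 7, 45 and 5 miR824 reads tailed in Col replicates 1, 2 and 3, and 6.98%, 2.08% and 2.43% of miR159 reads, and without it their means were 3.33% and 2.26%. In Ler, miR159 was tailed at 7.55% and 7.41% in replicates 1 and 2, where A was read as C, and at 1.94% in replicate 3. Among miRNAs with lower mutant shares, miR403, which targets AGO2, rose from 1.36% to 7.09% in hen1-1 and from 2.87% to 6.73% in hen1-8. There also miR162, which targets DCL1, rose from 8.54% to 11.2% in hen1-1 (edgeR adjusted p = 0.0208). Lower still was miR839, outside the naming rule, with 1.96% in Ler and 2.16% in hen1-1 and no call. In hen1-8 miR162 had 7.88% in Col and 9.86% in the mutant, with an edgeR adjusted p of 0.0610. Of miR399b, 0 of 137 Col reads were tailed, which allows a share of up to 2.19%, and 8.65% ± 3.49 (SD, n = 3) were in hen1-8.

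Tailing rose by the edgeR test in 26 of 27 miRNAs in hen1-1 and in 22 of 27 in hen1-8, and in 0 did it fall. By list, it rose in hen1-1 in 19 of 19 conserved miRNAs, 6 of 7 Brassicaceae miRNAs, 3 of 3 silencing regulators, 3 of 3 siRNA triggers, 4 of 4 auxin regulators, 3 of 3 nutrient miRNAs, 10 of 10 developmental regulators and 3 of 3 miRNAs with a 5′ A, and in hen1-8 in 15, 6, 2, 3, 4, 1, 9 and 2 of them, with the same counts adjusted over the list alone. No member of the 5′ C list had enough reads. The nutrient list of hen1-8 ranked below the other miRNAs by camera with the preset correlation (adjusted p = 0.0328), which was lost at adjusted p = 0.103 with an estimated correlation. Its members were divided, since miR399b rose by log2 6.34 while miR408 (0.89) and miR398 (-0.56) did not pass. Allowing truncation of up to 8 nt ended the tailing calls of miR165/miR166 in hen1-1 (log2 1.48, adjusted p = 0.0776, edgeR) and in hen1-8 (log2 1.62), of miR162 in hen1-1 and of miR158 in hen1-8.

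By odds ratio truncation rose most in miR165/miR166, where it went from 2.57% of reads in Ler to 71.6% in hen1-1 (log2 odds ratio 6.58, SE 0.23, edgeR adjusted p = 6.24e-12) and from 4.00% in Col to 66.4% in hen1-8 (5.61, SE 0.22, edgeR adjusted p = 3.98e-11). It rose in miR167, a regulator of auxin response factors, from 43.9% to 92.5% and from 43.3% to 90.3%, and in miR160, of the same pathway, from 38.2% to 92.6% and from 51.2% to 88.9%. In miR168, which targets AGO1, it rose from 12.7% to 38.8% in hen1-1 (log2 2.27, and 3.44 with C over A counted as a match), where the Ler value comprised 16.6% and 16.4% in the replicates with A read as C and 5.09% in replicate 3. By contrast miR390, which triggers TAS3 siRNAs and is loaded into AGO7, had 1.44% truncated reads in Ler and 0.907% in hen1-1, and 1.99% in Col and 1.03% in hen1-8, with no call in either allele. Truncation of miR161.2, with 78.3% in Ler and 80.6% in hen1-1, passed the test in neither allele. The missing bases of miR165/miR166 were mostly 1 nt in 31.1% ± 0.548 and 2 nt in 27.6% ± 2.19 of hen1-1 reads (SD, n = 3).

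Truncation rose in 19 of 27 miRNAs in hen1-1 and in 19 of 27 in hen1-8, and fell in 0. By list, it rose in hen1-1 in 13 of 19 conserved miRNAs, 5 of 7 Brassicaceae miRNAs, 2 of 3 silencing regulators, 1 of 3 siRNA triggers, 3 of 4 auxin regulators, 1 of 3 nutrient miRNAs, 8 of 10 developmental regulators and 0 of 3 miRNAs with a 5′ A. In hen1-8 the list counts were equal, except that adjusted over the list alone the nutrient list had 0. The 5′ A miRNAs (miR172a, miR390, miR408) lay below the others in hen1-1 by camera (adjusted p = 0.00275), which became adjusted p = 0.0535 with an estimated correlation. Across the 27 miRNAs the mutant shares of both alleles were close, with r = 0.993 and rho = 0.985 for tailing and r = 0.991 and rho = 0.992 for truncation. Without the 2 miRNAs farthest from the median r was 0.991 and 0.988. The permutation p was 1e-05 for each, the smallest that 100000 permutations give, and 2.5e-05 adjusted over 20 relations. For the rises alone r was 0.956 and 0.958.

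**Figure D2:**
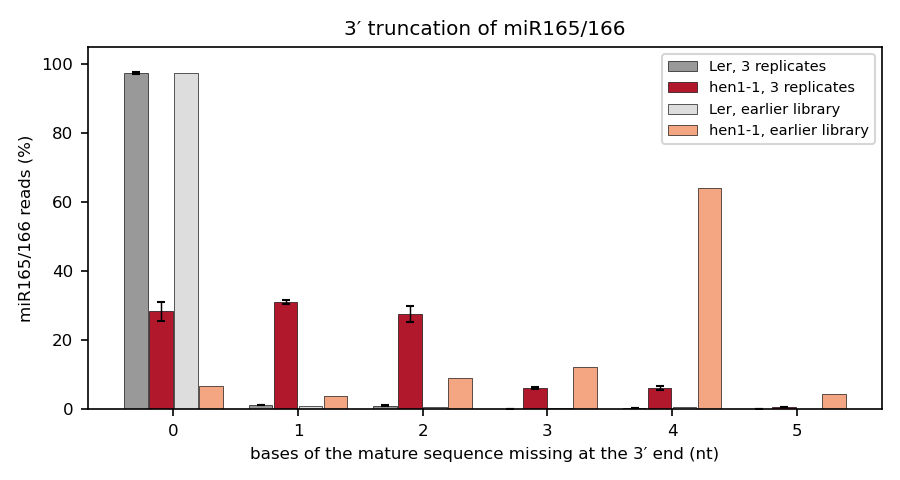
Percentage of miR165/miR166 reads (y axis) by the number of bases missing from the mature 3′ end (x axis, nt) in Ler and hen1-1 flowers, as means of 3 replicates with SD error bars, and in the earlier single libraries without error bars. In the replicated hen1-1 libraries 31.1% of reads had lost 1 nt, while in the earlier library 64.2% had lost 4 nt. A read that had lost 5 nt and gained U counts as 4 nt lost.

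Levels of miRNAs, with truncated and tailed forms included, moved in both directions. miR393, which targets the TIR1 and AFB auxin receptors, rose from 15.5 to 301 RPM in hen1-1 (log2 4.26, SE 0.58, edgeR adjusted p = 2.29e-05, n = 3) and from 28.03 to 464 RPM in hen1-8 (log2 4.04, SE 0.57, edgeR adjusted p = 3.99e-05). Without Ler replicate 3 the Ler mean of miR393 was 9.82 RPM, on 20 and 27 reads. miR160 rose by log2 2.73 (SE 0.45) and 2.78 (SE 0.45), miR824 by 1.90 and 2.18, miR167 by 1.62 and 1.88, and miR162 by 1.62 and 1.91. Levels of miR159 fell by 1.28 (SE 0.34) and 1.45 (SE 0.34) on the log2 scale. miR165/miR166 fell from 36378 to 11888 RPM in hen1-1 (log2 -1.61, SE 0.39, edgeR adjusted p = 0.00337) and did not pass in hen1-8 (log2 -0.68). The silencing regulators miR168 (log2 -0.95, edgeR adjusted p = 0.0522) and miR403 (-0.46) passed in neither allele, nor did miR390 (-0.57 in hen1-1 and 0.68 in hen1-8).

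The edgeR test called 10 miRNAs in hen1-1, 7 higher and 3 lower, and 12 in hen1-8, 10 higher and 2 lower. By list, hen1-1 had 4 higher and 3 lower of 19 conserved miRNAs, 3 and 0 of 7 Brassicaceae, 1 and 0 of 3 silencing, 2 and 0 of 3 trigger, 3 and 0 of 4 auxin, 0 and 1 of 3 nutrient, 1 and 2 of 10 developmental, and 0 and 1 of 3 with a 5′ A. In hen1-8 these were 6 and 1, 4 and 1, 1 and 0, 2 and 0, 3 and 0, 2 and 0, 1 and 1, and 1 and 0. Adjusted over the list alone the conserved list had 5 higher and 4 lower and the silencing list 1 lower in hen1-1, and the Brassicaceae list had 5 higher and 2 lower in hen1-8. No list passed camera, and the auxin list came nearest in both alleles (adjusted p = 0.182 and 0.0937, and adjusted p = 0.670 and 0.789 with an estimated correlation). Blocked by replicate number, which pairs these libraries, 21 miRNAs passed in hen1-1, 13 higher and 8 lower, against 17 with TMM, 8 higher and 9 lower, and 18 with DESeq2, 9 higher and 9 lower. In hen1-8 TMM called 5 higher and 8 lower and DESeq2 10 higher and 7 lower, and counting exact mature reads alone gave 1 higher and 11 lower in hen1-1 and 3 higher and 10 lower in hen1-8, with miR160 (-0.64), miR167 (-2.17) and miR824 (-2.08) below their controls in hen1-1.

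To ask whether secondary siRNAs formed at miRNA targets, 21-nt reads were counted per gene. The 3 miR171 targets HAM1, HAM2 and HAM3, which encode GRAS factors that maintain shoot meristems, gained siRNAs in both alleles. HAM1 went from 4.25 ± 2.36 RPM in Ler to 119 ± 36.1 in hen1-1 (SD, n = 3), a log2 change of 4.75 (SE 0.50, edgeR adjusted p = 5e-19), and from 8.56 ± 4.18 in Col to 257 ± 74.5 in hen1-8 (4.91, SE 0.49, edgeR adjusted p = 1.61e-20). HAM2 rose by log2 4.91 (SE 0.50) and 5.15 (SE 0.51), and HAM3 by 4.57 (SE 0.51) and 4.92 (SE 0.50). MYB12, a regulator of flavonol synthesis that miR858 targets, rose by log2 5.64 (SE 0.64) on 5 Ler and 622 hen1-1 reads and by 4.33 (SE 0.56) in hen1-8. AT1G10120 had 0 reads in Ler and in Col and was at least 12.4-fold higher in hen1-1, with 84 reads, and at least 5.84-fold higher in hen1-8, with 73 reads. AT1G60400 had 1 read in Ler and 67 in hen1-1, a ratio of 29.7 with a counting interval of 5.16 to 1192, and rose by log2 3.203 (SE 0.61) in hen1-8.

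The map of 21-nt reads along the HAM genes placed them on both strands and almost wholly 3′ of the miR171 site. HAM1 (AT2G45160) lies on chromosome 2 at 18617862 to 18620451 in the TAIR10.1 reference, on the minus strand, with the site at 18619128 to 18619148 in the coding sequence. HAM2 (AT3G60630) lies on chromosome 3 at 22410240 to 22412663 with its site at 22411544 to 22411564, and HAM3 (AT4G00150) on chromosome 4 at 57140 to 59495 with its site at 58411 to 58431, both sites coding and both genes on the minus strand. In hen1-1 and hen1-8, 99.6% and 99.7% of HAM1 reads, 99.9% and 99.9% of HAM2 reads and 100% and 99.96% of HAM3 reads lay 3′ of the site, while 49.3%, 54.2% and 54.4% of each gene did. Antisense reads made up 60.9% and 53.7% for HAM1, 69.7% and 51.6% for HAM2, and 59.4% and 54.9% for HAM3. The reads comprised 370 and 620 distinct sequences for HAM1, 312 and 705 for HAM2, and 343 and 767 for HAM3. miR171a (UGAUUGAGCCGCGCCAAUAUC), annotated on chromosome 3 at 19073521 to 19073541, had 6.09% ± 5.47 22-nt forms in hen1-1 and 9.62% ± 3.29 in hen1-8, against 1.86% ± 2.38 in Ler and 0.483% ± 0.837 in Col (SD, n = 3). The share of miR171b, of the same family, ran the other way, with 22.6% ± 3.42 in hen1-1 against 33.1% ± 20.3 in Ler and 25.5% ± 3.59 in hen1-8 against 47.5% ± 21.03 in Col. These shares of miR171a and miR171b were not tested.

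**Figure D3:**
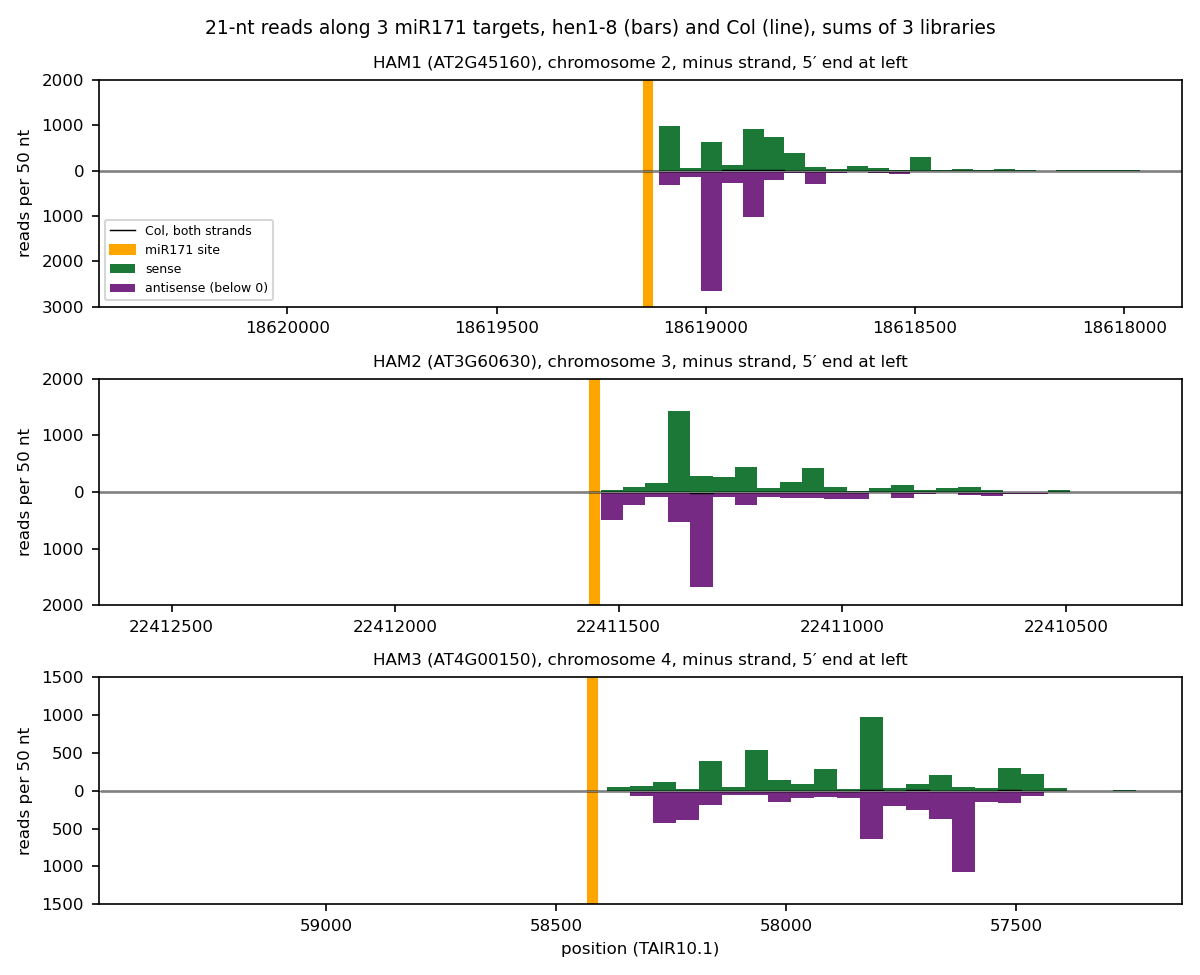
Reads of 21 nt per 50 nt (y axis, sums of 3 libraries) along HAM1, HAM2 and HAM3 (x axis, TAIR10.1 position, 5′ end at left) in hen1-8, with sense reads above and antisense reads below 0, Col as a thin line near 0 and the miR171 site in orange. No error bars are drawn; 99.7%, 99.9% and 99.96% of hen1-8 reads lay 3′ of the site.

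Of the TAS loci, which give rise to trans-acting siRNAs, 7 of 7 tested fell in hen1-1 and 6 of 7 in hen1-8, with the same counts adjusted over the list alone. Shortened or tailed siRNAs are mostly missed by the matching, both here and at the repeat genes below. The falls are thus losses of matched reads, and whether siRNAs with changed ends made up for them was not tested. TAS3, triggered by miR390, fell from 76.6 ± 34.8 to 5.13 ± 1.20 RPM in hen1-1 (SD, n = 3), a log2 change of -3.90 (SE 0.47), and by 1.80 (SE 0.42) in hen1-8. TAS1B fell by 4.09 (SE 0.50) and 2.72 (SE 0.44), TAS3b fell by 4.13 (SE 0.48) and 1.87, and TAS2 by 1.43 (SE 0.41) and 1.14 on the log2 scale. Of the pentatricopeptide repeat genes 6 of 6 tested fell in hen1-1 and 5 of 6 in hen1-8, with the same counts adjusted over the list alone. Among them AT1G63080 fell by 4.69 (SE 0.55) and 3.81 (SE 0.53), AT1G63070 by 6.08 (SE 0.64) in hen1-1, on 252 reads in Ler and 7 in the mutant, and AT1G63150 had 47 reads in Ler and 2 in hen1-1, a ratio of 53.0 with a counting interval of 13.9 to 450.03. In hen1-8 TASIR-ARF (log2 -0.54, edgeR adjusted p = 0.460) and AT1G63070, with 1 read in Col and 0 in the mutant, did not pass. In single libraries TAS reads lay higher in hen1-2 seedlings (3096 RPM against 1288 in Ler) and in the earlier hen1-8 flowers (9124 RPM against 1537 in Col).

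Camera called the TAS loci down (adjusted p = 7.55e-12 in hen1-1 and 9.26e-09 in hen1-8, and adjusted p = 0.0208 in hen1-1 and 0.0464 in hen1-8 with an estimated correlation), the repeat genes down (adjusted p = 1.72e-17 and 4.22e-14, and adjusted p = 0.00959 and 0.00952 with an estimated correlation) and the miR171 targets up (adjusted p = 2.12e-08 and 1.00e-09, and adjusted p = 0.0151 and 0.00952 with an estimated correlation). All 3 miR171 targets rose in each allele, also adjusted over the list alone. Of the targets of silencing regulators, AGO1 (log2 -0.14 and -0.46) and DCL1 were tested. DCL1 had log2 -1.41 in hen1-1 (edgeR adjusted p = 0.0707), called down adjusted over the list alone, and fell by 1.39 in hen1-8 (edgeR adjusted p = 0.0212). The list had adjusted p = 0.219 and 0.0438 by camera, and adjusted p = 0.393 and 0.184 with an estimated correlation. TCP4, a miR319 target, fell by 2.88 (SE 0.65) and 1.79, and was the tested member of the TCP and MYB list. The lists of miR393, ARF, HD-ZIP, SPL, AP2, GRF, NAC and nutrient targets had 0 tested members.

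In all, edgeR called 174 of 572 genes in hen1-1, 142 higher and 32 lower, and 193 in hen1-8, 162 higher and 31 lower. The split moved to 134 higher and 80 lower with TMM and 88 higher and 80 lower with DESeq2 in hen1-1, and to 118 and 109 with TMM and 95 and 74 with DESeq2 in hen1-8. Without hen1-1 replicate 3 or Ler replicate 2 the hen1-1 count was 101 or 112, and without Col replicate 2, hen1-8 replicate 2 or hen1-8 replicate 3 the hen1-8 count was 109, 113 or 124.

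The alleles were then compared by the difference between their effects. miR408 and miR398, copper-responsive miRNAs, rose in hen1-8, by log2 1.32 (SE 0.48) and 2.46 (SE 0.43), and the effects of hen1-1 lay lower by -2.47 (SE 0.64) and -2.26 (SE 0.57), each with an edgeR adjusted p of 0.0148. Those 2 calls became 0 without hen1-1 replicate 2, 4 with TMM or DESeq2 and 5 with a term for the run. The tailing effect of hen1-1 lay above that of hen1-8 for miR394 (log2 1.49, SE 0.42), miR403 (1.19, SE 0.27), miR319 (0.99, SE 0.26) and miR161.2 (0.89, SE 0.25), with edgeR adjusted p of 0.0289, 0.0241, 0.0289 and 0.0289. Their tailed shares were lower in Ler than in Col, at 2.84% against 7.57%, 1.36% against 2.87%, 13.9% against 28.8% and 8.76% against 16.7%. Shares in hen1-1 and hen1-8 lay closer, at 16.0% and 14.2%, 7.09% and 6.73%, 39.5% and 44.9%, and 34.8% and 37.6%. The larger effects thus go with lower control shares. These 4 tailing calls became 9 with U tails alone, 7 with C over A counted as a match, 2 with truncation of up to 3 nt and 0 with up to 8 nt, and 0 without Ler replicate 2 or hen1-1 replicate 3, 1 without Col replicate 1, hen1-8 replicate 2 or hen1-8 replicate 3, and 2 without Col replicate 3. For truncation 0 miRNAs passed in edgeR and 0 by limma, and 6 had an unadjusted p under 0.05 in edgeR. Matched reads at TAS3 and TAS3b fell further in hen1-1, with differences of -2.10 (SE 0.60) and -2.26 (SE 0.61), among 6 genes that passed. That count of 6 was 49 with TMM, 27 with DESeq2, 37 with the replicate block, 43 with the run term, 19 with 20- to 22-nt reads and 0 without a filter, and without 1 library it was 0 (hen1-1 replicate 2, hen1-1 replicate 3 or hen1-8 replicate 2), 1 (Ler replicate 3 or Col replicate 2), 2 (Col replicate 1 or hen1-8 replicate 3), 3 (hen1-1 replicate 1) or 10 (hen1-8 replicate 1). The nutrient list lay lower in abundance by camera (adjusted p = 0.00739, and adjusted p = 0.0673 with an estimated correlation), as did the 5′ A list (adjusted p = 0.0172, and adjusted p = 0.107 with an estimated correlation) and the TAS loci (adjusted p = 0.000108, and adjusted p = 0.414 with an estimated correlation). With the replicate block, which pairs libraries in abundance and truncation, 5 miRNAs passed for abundance and 4 for truncation, namely miR165/miR166 (0.97), miR158 (0.62), miR403 (1.10) and miR393 (1.60), and 4 passed for truncation without tailed reads, 3 with C over A counted as a match, 3 with the run term and 1 without Col replicate 1. Allele and background differ together here, so their parts cannot be told apart.

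Whether AGO1 is needed for tailing and truncation was addressed with seedlings, at 1 library per genotype and so with no replicate check. In hen1-2, 47.1% (Wilson 95% interval 46.98 to 47.2) of miRNA reads were tailed and 34.3% (34.2 to 34.4) truncated, against 9.51% (9.38 to 9.63) and 10.3% in Ler. All 23 miRNAs compared lay higher in hen1-2 for tailing. In ago1-11 hen1-2, whose AGO1 is impaired, the tailed share was 46.7% (46.4 to 47.04) and the truncated share 12.1% (11.9 to 12.3). The tails differed, with 52.4% U and 42.5% C among tail bases there, against 80.6% U and 16.0% C in hen1-2. Counted miRNA reads were 0.495% of the 18 to 28-nt reads in ago1-11 hen1-2 and 5.13% in hen1-2. Their share was 0.334% in ago1-11 and 1.04% in Ler. Single miRNAs moved apart. Truncation of miR165/miR166 was at 29.1% in the double mutant and 69.3% in hen1-2, and its tailing at 5.67% and 24.3%. Tailing of miR159 was at 14.9% and 36.5%, while that of miR162 was at 44.4% and 12.3%, that of miR158 at 78.0% and 49.2%, and that of miR156 at 79.6% and 77.4%. Tailing was higher in 8 and lower in 14 of 22 miRNAs, and truncation higher in 11 and lower in 11. In ago1-11 alone 8.94% (8.71 to 9.17) of reads were tailed and 5.03% (4.86 to 5.21) truncated. The pooled truncated share was thus lower with impaired AGO1 than without in both HEN1 states, but single miRNAs were divided. In ago1-11 against Ler, truncation was higher in 11 and lower in 8 of 19 miRNAs, with medians of 4.69% and 4.51%. The widest interval of a named miRNA reached 6.76 points to either side. The small pooled difference of -0.368 points turned to 11.4 when every base past the mature sequence counted as a tail and was -8.39 for the median miRNA.

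HESO1 adds U to unmethylated small RNAs, and its loss was examined in AGO1-bound reads, again with 1 library each. In the AGO1 precipitate of heso1-1 hen1-8, 13.9% (Wilson 95% interval 13.8 to 13.9) of miRNA reads were tailed, against 39.7% (39.6 to 39.7) in that of hen1-8, and 71.3% against 54.97% were truncated. Tailing was lower in 28 of 32 miRNAs, with 11.1% against 66.9% for miR161.1, 10.7% against 52.1% for miR167, and 9.55% against 37.4% for miR159. It was higher for miR158 (72.0% against 60.9%), miR156 (90.5% against 80.0%) and miR164 (73.0% against 35.7%). In the inputs 29.6% (29.2 to 29.9) and 36.3% (35.9 to 36.8) were tailed, with 15 of 16 miRNAs lower in the double mutant. The median input miRNA was at 17.1% in the double mutant and 30.2% in hen1-8. Between precipitate and input of hen1-8, tailing was 39.7% against 36.3% and higher in 12 of 16 miRNAs, with 60.2% against 29.6% for miR319 and 13.2% in each for miR165/miR166. Medians over miRNAs were 35.4% in the precipitate and 30.2% in the input. The widest interval among the named miRNAs reached 7.32 points, since the inputs held few small RNAs.

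In rice, tailed reads made up 63.5% (Wilson 95% interval 63.4 to 63.6) of miRNA reads in waf1-1 against 2.14% in its wild type, 72.5% (72.4 to 72.5) in waf1-2 against 2.38%, and 66.2% (66.1 to 66.3) in oshen1-3 against 4.09% in wild type and 1.95% in segregating heterozygotes. Truncated reads made up 55.2% against 1.48%, 57.2% against 7.14%, and 42.6% against 0.727%. miR528, a monocot miRNA, was tailed at 98.2%, 98.2% and 98.1% against 10.7%, 10.14% and 16.1%, and miR160 at 98.0%, 98.0% and 97.9%. miR168 was tailed at 76.0% and truncated at 6.47% in waf1-1, while miR165/miR166 was tailed at 78.1% and truncated at 79.8%. Tailing was higher in 24 of 25, 26 of 26 and 23 of 24 miRNAs. The exceptions were miR159, at 17.9% against 28.8% in waf1-1 and 57.2% against 86.5% in oshen1-3. In waf1-2 miR159 was truncated at 25.8% against 97.7% in wild type. Each genotype was 1 library, and the widest interval of the named values reached 4.18 points.

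Maize hen1-1 leaves had 40.2% (Wilson 95% interval 40.2 to 40.3) tailed and 51.6% truncated miRNA reads against 6.04% and 6.38% in wild type, at 1 library each and in different backgrounds. The median miRNA was tailed at 30.8% in the mutant and 8.38% in wild type. Tailing was higher in 15 of 17 miRNAs, with 94.0% against 11.6% for miR160, 84.4% against 12.2% for miR393 and 84.8% against 23.04% for miR159. It was lower for miR168 (30.8% against 41.0%) and miR529 (2.57% against 2.78%). Truncation was higher in 17 of 17 miRNAs, with 1.498% against 1.31% in miR168 and 95.2% against 11.3% in miR396e. The 24-nt class held 28.9% of reads in the mutant and 62.8% in wild type. Without a genome the templates of rice and maize held few bases past the mature sequence, and the widest interval of the named values reached 3.21 points.

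Species were compared over the 13 miRNAs shared by each pair. Mean mutant tailing of Arabidopsis flowers against rice had r = 0.222 and rho = 0.110 (permutation p = 0.5 and 0.7), against maize r = 0.496 and rho = 0.275 (permutation p = 0.08 and 0.4), and rice against maize r = 0.239 and rho = 0.313 (permutation p = 0.4 and 0.3). For truncation these were r = 0.191 and rho = 0.0495, r = 0.473 and rho = 0.269, and r = 0.607 and rho = 0.5, the last with permutation p = 0.03 and 0.09 and adjusted p of 0.0667 and 0.164, and with r = 0.306 without 2 miRNAs. Without 2 miRNAs r was 0.742 for tailing in rice against maize, 0.108 for tailing in Arabidopsis against rice, and 0.711 for truncation in Arabidopsis against maize, so these relations rest on few miRNAs. miR168 was truncated at 35.4% in Arabidopsis, 5.58% in rice and 1.498% in maize, and miR167 at 91.4%, 32.0% and 9.21%. In the Arabidopsis controls Ler and Col, miR168 was already truncated at 12.7% and 12.9% and miR167 at 43.9% and 43.3%. miR165/miR166 was truncated at 69.0%, 74.9% and 69.6% and tailed at 12.1%, 75.0% and 41.7%. In the earlier Arabidopsis flower libraries it was tailed at 77.3% in hen1-1 and 77.7% in hen1-8. The tailing gap of miR165/miR166 between species thus depends on the set of Arabidopsis libraries. Tissue and template differ with species, and genomic templates were used for Arabidopsis alone.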

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

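The tests chosen only after the result was seen were those on A read as C and on the runs, on the register of single HAM genes, on the side of the miR171 site, and on the earlier flower libraries. Those on single sequences, antisense reads, the register of all HAM genes together and the splits of the libraries were set before.

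The first pattern was the rise of tailing and truncation in both alleles. With C over a template A counted as a match, at least 98.1% of each of the 4 rises in the pooled tailed and truncated shares was kept, and within either run at least 88.8%, which argues against misread bases and the runs as the source. The libraries contrast mutants of the methyltransferase with controls, so lost methylation remains a candidate explanation, although methylation was not measured here. Pooled tailed shares were also higher in the single HEN1 mutant libraries of seedlings, rice, maize and the earlier flowers than in their controls. The 3 against 3 libraries make 10 splits, too few for a share under 0.05. Only 1 of the 10, the real one, reached the real count for abundance (10 in hen1-1 and 12 in hen1-8), tailing (26 and 22), truncation (19 and 19) and genes (174 and 193), and the highest other split gave 0 calls, or 2 for genes in hen1-1.

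The second pattern was the rise of 21-nt reads at HAM1, HAM2 and HAM3. No single sequence held over 22.9% of the reads of a gene, and at least 51.6% were antisense in each gene and allele, which argues against a few sequences unique to the gene and against fragments of the transcript, while miR171a reads match all 3 genes and were not counted. At least 99.6% lay 3′ of the site, as siRNAs made from the 3′ part of the transcript would. A start of dicing at the cleavage site was open for the genes together, with 1.83% of reads in its register at the lowest. By gene, hen1-1 and hen1-8 had 21.9% and 21.9% in HAM1 against 4.76% for 1 register, where such dicing may occur, 5.83% and 10.8% in HAM2, on either side of 2 times that share, which decides nothing, and 2.92% and 1.83% in HAM3, which argues against it.

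The third pattern was the earlier flower set, which stands outside the replicated comparison. Its tailed shares were 69.9% in hen1-1 and 55.02% in hen1-8, against 2.40% and 5.35% in its Ler and Col. The earlier Ler and Col libraries differed by -2.86 and -2.98 points from the lowest replicated library of their own background, which argues against a preparation that raises tailing in every genotype but not against one acting on mutants alone; this comparison was chosen after one over both backgrounds had put the earlier Col 0.0902 points above a Ler library. With the miRNA mix of the replicated libraries 48.8% of the hen1-1 difference was kept, so the mix could account for part of it. Within miR165/miR166 the tailed share was 77.3% in the earlier hen1-1 library and 12.9% in the replicated ones, a gap that the mix across miRNAs does not make. In hen1-8, 118% was kept, which argues against the mix there.

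The same set gave 267 RPM of 21-nt reads at the HAM genes in hen1-1 against 13.9 in Ler, and 7828 RPM in hen1-8 against 24.7 in Col, in libraries not used in the tests of the replicated set. At TAS loci the earlier hen1-8 library went against the replicated hen1-8 libraries, with 9124 RPM against 1537 in its Col. A wrong label of that library was not tested, so its HAM value is no independent repeat.

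The remaining results were picked out because the hen1-1 effect and the hen1-8 effect differed by the edgeR test of the difference itself. For abundance these were miR408 (-2.47) and miR398 (-2.26), 2 calls in all, and 8 of 100 splits gave as many, up to 10, so chance cannot be excluded, and 0 passed without hen1-1 replicate 2, 4 with TMM or DESeq2 and 5 with the replicate block or the run term. Both miRNAs stood lower in Col (3.71 and 8.91 RPM) than in Ler (60.2 and 144 RPM). For tailing these were miR394 (1.49), miR403 (1.19), miR319 (0.99) and miR161.2 (0.89), and 4 of 100 splits gave as many as these 4 calls, up to 6. That share is under 0.05, but these splits also mix Ler with Col libraries, so chance cannot be excluded. Tailing of these 4 miRNAs was lower in Ler than in Col and lay closer between the mutants. The count itself was unstable, with 9 calls for U tails alone, 7 with C over A counted as a match, 2 with truncation of up to 3 nt and 0 with up to 8 nt, and 0 without Ler replicate 2 or hen1-1 replicate 3, 1 without Col replicate 1, hen1-8 replicate 2 or hen1-8 replicate 3, and 2 without Col replicate 3. For truncation 0 calls were made, so 100 of 100 splits had to give as many (highest other 3), which tests nothing. For genes the 6 calls were AT4G20735 (-4.95), AT5G04245 (-4.37), AT5G33075 (-3.89), TAS3b (-2.26), TAS3 (-2.10) and AT3G07855 (2.65). In 7 of 100 splits as many genes passed, so chance cannot be excluded, and 1 split gave 233, which points to a structure of the libraries. That split set the 3 hen1-1 libraries against 1 Ler and 2 Col libraries, so differences between the backgrounds enter its count. With TMM the 6 became 49, with DESeq2 27, with the replicate block 37, with the run term 43, with 20- to 22-nt reads 19 and without a filter 0. Without 1 library they became 0 (without hen1-1 replicate 2, hen1-1 replicate 3 or hen1-8 replicate 2), 1 (Ler replicate 3 or Col replicate 2), 2 (Col replicate 1 or hen1-8 replicate 3), 3 (hen1-1 replicate 1) or 10 (hen1-8 replicate 1). In hen1-1, AT4G20735 had 1 read, AT5G04245 1 read and AT5G33075 3 reads, so their fitted differences rest on few reads and are no bounds.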

How the results depend on the processing

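The tests chosen only after the data had been seen were those with joined reads kept, with C over A counted as a match, with a term for the run, within runs, and without the 2 farthest miRNAs in the correlation. Over 29 results, 128 of 172 values stayed on their side or within their spread, 42 moved and 2 reversed. Among named miRNAs and genes 3182 of 3438 values kept their call or lack of a call, 93 gained and 154 lost a call, and 9 reversed. A change of sign counted as a reversal only where the main or the alternative fit called the value. The cause was not tested for any change below, except where fewer reads or genes enter by construction. Low counts limit the gene tests, and low input depth the AGO1 inputs.

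For abundance in hen1-1 the main count was 10, and TMM gave 17, DESeq2 18, the replicate block 21 and the run term 18. With exact mature reads alone miR161.2 (-1.21), miR160 (-0.64), miR824 (-2.08) and miR167 (-2.17) reversed in hen1-1 and miR161.2 (-0.44) and miR824 (-1.60) in hen1-8, where truncated and tailed reads no longer counted. With truncated reads counted to 8 nt the abundance of miR163 in hen1-8 was at log2 0.54, in reverse. The difference between alleles in abundance went from 2 calls to 4 with TMM, 4 with DESeq2, 5 with the replicate block and 5 with the run term. In tailing it went from 4 to 9 with U tails alone, 2 with truncation to 3 nt, 0 to 8 nt and 7 with C over A matched, with miR168 reversed at 1.23 and 0.99 for U tails and for C over A. In truncation it went from 0 to 4 with the replicate block, 4 without tailed reads, 3 with C over A matched and 3 with the run term. For genes, hen1-1 went from 174 to 115 without a filter, hen1-8 from 193 to 369 with reads at every gene and 327 with the run term, and the difference from 6 to 49 with TMM, 27 with DESeq2, 0 without a filter, 37 with the replicate block, 19 with 20- to 22-nt reads and 43 with the run term. The block moved no other count by over 1.5 times. Same-numbered libraries did not correlate throughout in tailing, and in reads per gene they did so only weakly, with r between 0.0150 and 0.212.

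The 24-nt difference of hen1-8 reversed to 4.60 points as a share of all reads. The tailed difference of ago1-11 hen1-2 was 11.4 with mature-only templates, in reverse, and -8.39 as a median. The AGO1 precipitate differed from input by 5.22 as a median. For heso1-1 hen1-8 the difference was -25.2 with mature-only templates and -23.9 as a median, and -13.1 as a median in the inputs. With mature-only templates, truncation to 8 nt and the median the differences were 50.5, 60.9 and 62.8 points in waf1-1, 48.5, 69.99 and 70.4 in waf1-2, 53.6, 61.8 and 75.7 in oshen1-3, and 32.0, 35.9 and 22.4 in maize.

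Leaving out each library in turn gave 8 to 12 calls in hen1-1, 9 to 12 in hen1-8 and 0 to 2 for the difference in abundance, 23 to 26, 21 to 22 and 0 to 6 in tailing, 17 to 19, 18 to 20 and 0 to 1 in truncation, and 101 to 169, 109 to 255 and 0 to 10 in genes. The 21-nt difference stayed between -6.15 and -4.16 and between -4.67 and -3.36 points, the 24-nt difference between -10.6 and -8.76 and between -2.96 and -0.605, the tailed difference between 27.5 and 33.6 and between 23.7 and 26.5, and the truncated difference between 49.1 and 50.8 and between 41.6 and 44.1.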

Other observations

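Every value in this part was chosen after the data had been seen, and no test was run on it. In AGO1 precipitates the HAM siRNAs stood at 1489 RPM in hen1-8 and 2063 RPM in heso1-1 hen1-8, against 328 and 578 RPM in the inputs. In seedlings they stood at 56.6 RPM in hen1-2, 0.753 in ago1-11 hen1-2, 0.926 in ago1-11 and 0.772 in Ler. Reads at TAS loci stood at 3096 RPM in hen1-2 and 1288 in Ler seedlings, a direction opposite to the replicated flowers, and at 117 RPM in ago1-11 hen1-2 and 284 in ago1-11. In the AGO1 precipitates TAS reads stood at 4560 RPM in hen1-8 and 470 in heso1-1 hen1-8.

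In the earlier flower set TAS reads stood at 254.6 RPM in hen1-1 and 3742 in Ler, but at 9124 RPM in hen1-8 and 1537 in Col, opposite to the replicated hen1-8 libraries, where they were at 345, 734 and 708 RPM against 748, 1458 and 2107 in Col. Reads at the pentatricopeptide repeat genes stood at 9.34 RPM in the earlier hen1-1 library and 258 in its Ler, and at 125 RPM in hen1-8 and 103 in Col. The 21-nt class held 20.8% of reads in the earlier hen1-8 library and 17.5% in its Col, and 9.30% in hen1-1 and 15.7% in Ler.

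In rice the 24-nt class held 11.5% of reads in waf1-1 and 33.5% in its wild type, 11.2% and 28.2% for waf1-2, and 17.8% and 35.7% for oshen1-3. In rice oshen1-3 and its wild type 1.06% and 1.10% of A bases were read as C. Of miR171a reads 24.1% had 22 nt in maize hen1-1 and 1.35% in wild type, 29.7% in waf1-1, 28.8% in waf1-2 and 44.3% in oshen1-3.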
